A study of Mus musculus with 24 samples.

How the data were processed

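The series holds 24 mouse samples, 6 from each of RNA-seq of B16-OVA tumour cells, RNA-seq of co-cultured OT-I CD8 T cells, ATAC-seq of the tumour cells, and m6A-seq of the tumour cells. Of the m6A-seq samples, 3 are antibody libraries whose peak lists were used, and the matching inputs have no file of their own. RNA libraries came from a stranded total RNA kit, ATAC-seq libraries from a transposase kit and m6A libraries from an antibody enrichment kit, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.0, Bowtie2 2.3.5, STAR 2.7.0f, deepTools, Picard and MACS2 2.1.3 and the mouse build mm10, without saying which step used which. The tool that counted reads, its strand setting, the annotation and the peak thresholds are not stated in the sources used here.

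The deposited RNA-seq tables hold raw counts per gene symbol, 1 column per library, per the file headers. The deposited ATAC-seq lists give, for each peak of 1 library, a fold enrichment ratio, the -log10 p and -log10 q, and a score that is 10 times the -log10 q. The deposited m6A lists are exomePeak output per the labels, with a fold enrichment ratio of antibody over input, a p-value, and log10 scores of the p-value and false discovery rate for each peak. These fold enrichments are the peak callers' values, and their differences between libraries were not tested.

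Samples were grouped by their labels: shFto and shNC tumour cells, and T cells beside shFto-1, shFto-2 and shNC cells. The labels of the tumour RNA-seq, ATAC-seq and m6A-seq samples do not say which of the shFto lines was used. Groups, comparisons, tests, 31 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Of the lists, the mitochondrially encoded messenger RNAs could not be tested, because 0 of 13 were in either table.

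Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, default expression filter), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Tumour and T cell libraries were fitted apart. The T cell contrasts were the mean of both shFto lines against shNC, each line against shNC, and the lines against each other, in 1 fit of 6 libraries. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the 23 lists of each comparison, and again with the correlation estimated from the residuals. List counts are given by the adjustment over all genes and adjusted over the list alone.

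Named genes were Fto, Jun, Junb and Cebpb, up to 3 members of each list with the smallest adjusted p, and the 8 largest rises and falls. The latter needed an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the sides, and left out predicted and Rik symbols. Some genes that the rule names are not reported here. Genes outside the rule are given as chosen after their values were seen. Where a group had no counts, the fold change is given as a bound against 3 counts over that group. Where it had few, a CPM ratio with an exact interval is given.

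ATAC-seq peaks were merged over the 6 libraries with an overlap of 1 bp, after keeping in each library as many peaks, ranked by -log10 q, as the smallest list holds (67427). A region counted as shFto-only or shNC-only with a peak in all 3 libraries of that group and none of the other. Peak numbers were compared by exact permutation, 3 against 3. The plan used the nearest transcription start within 50 kb. Because strand was known for 58.9% of the tested genes only, from the m6A lists, the nearest end of a protein-coding gene was used instead. Of 11718 tested genes, 11675 (99.6%) were placed on the annotation and 11212 were protein-coding. RNA differences were tested with 100000 permutations across genes. For m6A, genes with no shNC peak were sorted by peaks in the shFto and Dac51 lists, with Fisher's exact test, and their RNA change was set against permutations within 10 expression bins. These steps used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3, and figures Matplotlib 3.10.9.

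The spread between libraries, as the common biological coefficient of variation, was 0.0906 for tumour cells and 0.199 for T cells. The 10 most abundant genes took 4.17% to 4.63% of counts in tumour libraries and 5.75% to 6.93% in T cell libraries. The pipeline was tested on simulated data. With the depth and spread of the tumour libraries it recovered 90% of genes changed 2-fold and 96% of those changed 4-fold, and 5.10% of its calls were false. For T cells these were 66%, 71% and 8.05%, and 88.4% and 94.1% were recovered at 10 CPM or more. Each simulation changed 200 genes, as many up as down, with genes drawn independently. It does not test scaling or false calls where as many genes change as in these data. The peak steps found all 700 and 500 group-only regions placed in simulated lists, and 2 of 40 null gene sets had a permutation p under 0.05.

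Alternatives were relative log expression scaling, library totals, no expression filter, a filter of at least 1 CPM, a block for replicate number, DESeq2 1.42.0, a 2-fold threshold, each library left out, camera with an estimated correlation, the fry set test, other peak thresholds and overlaps, and other distances. Added after the data were seen were thinning of all T cell libraries to 2628158 counts, the T cell fit without genes that tumour RNA can account for, crossed replicate numbers, and transcription starts of genes with a known strand. Tumour RNA was taken to account for a T cell gene when the tumour cell level times the tumour share reached a fraction of at least 0.5 of the T cell level. That share was the median of T cell over tumour cell level across melanocyte genes of at least 100 CPM. Without a genome sequence, motif and transcript location analyses were not run.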

Results

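The series profiled B16-OVA cells, a mouse melanoma line that carries the ovalbumin antigen, after knockdown of Fto, and the CD8 T cells that had met them. FTO is an enzyme that removes N6-methyladenosine (m6A), the commonest internal mark of messenger RNA. Cells with a hairpin against Fto (shFto) were set against cells with a control hairpin (shNC). RNA-seq covered 3 shFto and 3 shNC tumour libraries. It also covered OT-I CD8 T cells, whose receptor recognises an ovalbumin peptide, sorted after 8 h with shNC, shFto-1 or shFto-2 tumour cells, with 2 libraries each. ATAC-seq, which maps open chromatin by transposase insertion, covered 3 shFto and 3 shNC tumour libraries. For m6A-seq, RNA bound by an m6A antibody gave 1 peak list each for shNC cells, shFto cells and shNC cells treated with 5 µM Dac51. The labels give a treatment time of 48 h for all 3. Dac51 is named only by that code, and its target is not stated in the labels. Total counts were 18330689, 11152404 and 19665589 in the shFto tumour libraries and 13413981, 17406625 and 14671458 in the shNC ones. The T cell libraries held 13066355 and 5166653 for shFto-1, 9294666 and 6549224 for shFto-2, and 2628158 and 6567685 for shNC. The labels do not say that libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

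Fto itself, an RNA demethylase gene on mouse chromosome 8 (91313367 to 91668433, mm10), fell in the tumour cells that carried the hairpin. Its level was 31.2 ± 2.65 CPM (TMM-scaled counts relative to library size; SD, n = 3) in shFto and 103 ± 9.32 CPM (SD, n = 3) in shNC cells, a log2 fold change of -1.72 (SE 0.0979, edgeR quasi-likelihood adjusted p = 1.6e-10). The shFto libraries gave 31.7, 33.5 and 28.3 CPM, and the shNC libraries 107, 108 and 91.8 CPM. In the co-cultured T cells, which were not the target of the hairpin, Fto lay at 42.5 and 38.7 CPM beside shFto-1, 50.0 and 50.5 CPM beside shFto-2, and 36.1 and 47.1 CPM beside shNC tumour cells. That difference did not pass the test (log2 fold change 0.09, SE 0.133, edgeR adjusted p = 0.648).

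**Figure D1:**
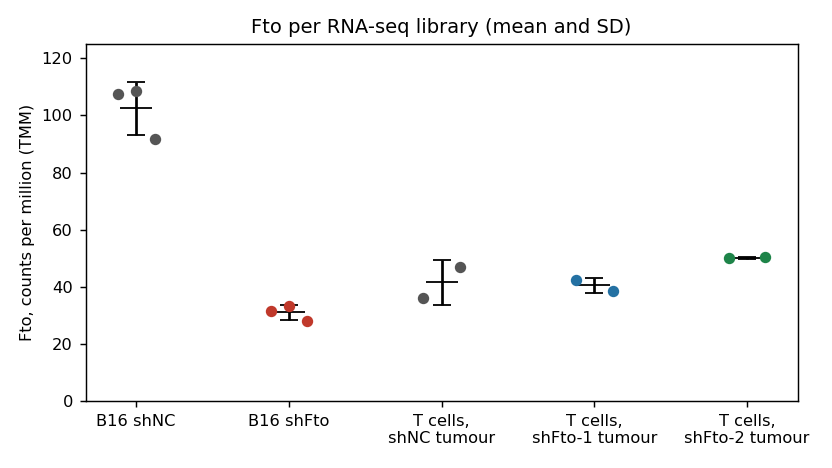
Fto in each RNA-seq library, in TMM-scaled CPM on a linear axis from 0, with dots for libraries and bars for the mean and SD of each group. The 3 shFto tumour libraries lie between 28.3 and 33.5 CPM, below the 3 shNC tumour libraries at 91.8 to 108 CPM, while the 6 T cell libraries lie between 36.1 and 50.5 CPM.

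The first comparison asked what Fto knockdown changed in tumour cells. Pigment cell transcripts rose: Oca2, a melanosome transport protein gene on chromosome 7 (56239593 to 56536518, mm10), went from 7.77 ± 0.672 to 43.7 ± 0.514 CPM (SD, n = 3 each; log2 fold change 2.5, SE 0.121), and the channel gene Trpm1 from 60.7 ± 6.10 to 256 ± 5.68 CPM (2.08). All 15 measured replication-dependent histone genes, 23 of 36 ribosomal protein genes and 14 of 25 glycolysis genes fell, while 3 glycolysis genes rose. These list calls were lost at adjusted p = 0.151, 0.451 and 0.451 with an estimated correlation. The fry set test called histones (adjusted p = 0.00398) and glycolysis (0.0404) but not ribosomal proteins (0.0582). Fry asks whether a list changed at all, and camera whether it changed more than other genes. A fry call therefore does not restore a lost camera call. Prkg2, a cGMP-dependent protein kinase gene on chromosome 5 (98929773 to 99037375, mm10), had the largest named fall, from 33.4 ± 3.6 to 5.05 ± 1.05 CPM (-2.72). The other named rises by size were the sodium-calcium exchanger gene Slc24a4 (log2 fold change 2.49), the transcriptional inhibitor Id3 (2.39), the cystine transporter Slc7a11 (2.14), the BMP effector Smad9 (1.99), the semaphorin Sema6d (1.80) and the nuclear receptor Nr4a3 (1.79). The other named falls were the collagen Col9a1 (-2.22), Fam178b (-2.12), Sema6a (-1.92), Tenm4 (-1.81), the actin bundler Espn (-1.76), Afap1l2 (-1.75) and the myelin protein gene Mbp (-1.74). Their edgeR adjusted p-values ran from 4.39e-12 for Trpm1 to 1.09e-06 for Afap1l2.

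Of 16 measured melanocyte lineage genes, 12 rose and none fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.51. Besides Oca2 and Trpm1, the tyrosinase gene Tyr rose from 77.0 to 200 CPM (1.37). The camera set test gave this list an adjusted p of 2.43e-18, and adjusted p = 0.0487 with an estimated correlation. It was the only tumour cell list called under both. Of 21 targets of the stress factor ATF4, 10 rose and 2 fell (11 and 3 adjusted over the list alone), among them Slc7a11, Atf5 (0.87) and Ddit3 (0.70), the last 2 being stress transcription factors. This list had a camera adjusted p of 0.00507, and adjusted p = 0.178 with an estimated correlation. Of 18 endoplasmic reticulum chaperones, 8 rose (9 adjusted over the list alone), including Pdia3 (0.33), Dnajc3 (0.33) and Canx (0.36). That list had a camera adjusted p of 0.0169, and adjusted p = 0.451 with an estimated correlation.

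Of 25 glycolysis genes, 14 fell and 3 rose (16 and 3 adjusted over the list alone), with a median of -0.42. Hexokinase 1 (Hk1, -0.59), phosphoglycerate kinase (Pgk1, -0.64) and phosphoglycerate mutase (Pgam1, -0.75) fell. The members that rose were the lactate transporter Slc16a1 (0.56), the glucose transporter Slc2a3 (0.34) and the enolase Eno2 (0.98), named here after their values were seen. Camera gave glycolysis an adjusted p of 0.00168, and adjusted p = 0.451 with an estimated correlation. The median was -0.27 without shNC replicate 3. Of 20 hypoxia response genes, 10 fell and 1 rose (12 and 2 adjusted over the list alone), including the oxygen sensor Egln1 (-0.85) and the mitophagy genes Bnip3l (-0.84) and Bnip3 (-1.21), the last not passing DESeq2 (adjusted p = 0.0816). Its camera adjusted p was 0.00564, with adjusted p = 0.451 with an estimated correlation and adjusted p = 0.0540 without shFto replicate 3, and it did not pass fry (0.0853).

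All 15 measured replication-dependent histone genes fell (15 adjusted over the list alone), with a median of -1.11, including the linker histones Hist1h1c (-0.90) and Hist1h1d (-1.11) and the core histone Hist1h2ac (-1.44). The list had a camera adjusted p of 3.63e-09, and adjusted p = 0.151 with an estimated correlation. Of 36 cytosolic ribosomal protein genes, 23 fell and none rose (24 and 0 adjusted over the list alone), with a median of -0.38, among them Rps6 (-0.97), Rplp1 (-0.62) and Rpl18 (-0.72). Camera gave them an adjusted p of 2.13e-08, and adjusted p = 0.451 with an estimated correlation. They did not pass fry (0.0582), and their median was -0.24 without shNC replicate 3. Histone, ribosomal protein and class I MHC genes share sequence with near-identical copies, so single members are uncertain.

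Of 23 extracellular matrix and mesenchymal genes, 11 fell and 5 rose (12 and 5 adjusted over the list alone). The collagens Col4a1 (-1.49) and Col5a1 (-1.06) fell, while the matrix protein gene Sparc rose (0.80). The list had a camera adjusted p of 0.0112, and adjusted p = 0.451 with an estimated correlation. Of 36 nuclear-encoded oxidative phosphorylation genes, 10 fell and none rose (10 and 0 adjusted over the list alone), including Cox5b (-0.61), Ndufs7 (-0.57) and Cyc1 (-0.46). Its camera adjusted p was 0.0169, and adjusted p = 0.604 with an estimated correlation. The call ended without shFto replicate 3 (camera adjusted p = 0.0783) and without shNC replicate 3 (0.284; median -0.02), and the list did not pass fry (0.191). The median of -0.08 became -0.14, -0.13 and -0.16 without shFto replicate 2, shNC replicate 1 and shNC replicate 2.

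The other tumour cell lists did not pass camera. Of the class I antigen presentation genes, 8 of 18 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0637), and H2-Q4 (1.07), H2-D1 (0.72) and B2m (0.48) were among those that rose. This list passed camera without shFto replicate 1 (adjusted p = 0.047), without shNC replicate 1 (0.0447), without shNC replicate 3 (0.0383) and with no filter (0.0272), and passed fry (0.00839). Of 13 AP-1 and C/EBP transcription factors, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.594). Jun (-0.59), Jund (-0.74) and Atf3 (-1.04) fell, whereas Junb (0.11, SE 0.138, adjusted p = 0.583) and Cebpb (-0.37, SE 0.172, adjusted p = 0.107) did not pass edgeR's test. Cebpb passed it without shFto replicate 3 (adjusted p = 0.0161) and without shNC replicate 2 (0.0351). Of 32 interferon-stimulated genes, 5 rose, including Cxcl10 (0.56) and Irgm1 (0.49), and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.776). Of 14 tumour chemokine, cytokine and growth factor genes, 3 rose and 4 fell, the latter including Mif (-0.63) and Pdgfa (-0.72) (3 and 4 adjusted over the list alone; camera adjusted p = 0.465). Of 7 checkpoint ligand and adenosine genes, Lgals9 (0.43) and Pvr (0.33) rose (2 adjusted over the list alone; camera adjusted p = 0.314), and Cd274, which encodes PD-L1, had a value of 0.44 (adjusted p = 0.0981). The Pvr call ended without shFto replicate 2 (adjusted p = 0.0733) or without shNC replicate 2 (0.0659).

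Among the remaining lists, 12 of 38 S and G2/M phase genes fell and 8 rose (12 and 8 adjusted over the list alone; camera adjusted p = 0.264), with Ube2c (-0.58), Kif20a (-0.54) and Cdc20 (-0.51) among the falls. Of 17 p53 targets, 5 rose, including Ccng1 (0.51) and Mdm2 (0.41), and Gdf15 fell (-1.41) (5 and 3 adjusted over the list alone; camera adjusted p = 0.314). Of 13 heat shock genes, 4 rose, including Hspb1 (0.82), Chordc1 (0.56) and Hspd1 (0.33) (4 adjusted over the list alone; camera adjusted p = 0.314). Of 20 sterol genes, 7 rose, including Sc5d (0.78) and Dhcr7 (0.55), and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.174). Of 12 fatty acid synthesis genes, 3 rose, including Me1 (0.63) and Elovl5 (0.42), and 4 fell, including Srebf1 (-0.78) (3 and 6 adjusted over the list alone; camera adjusted p = 0.421). Of 20 MYC and ribosome biogenesis genes, 6 fell, including Odc1 (-0.49), Fbl (-0.48) and Ppan (-0.52), and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.105). Of 18 m6A writers, erasers and readers, Fto and 4 others fell, including Rbm15b (-0.47), and the reader Ythdf3 rose (0.60) (6 and 1 adjusted over the list alone; camera adjusted p = 0.0809). This list passed camera without shNC replicate 3 (0.0314) and with no filter (0.0498). Markers foreign to the culture were few: 3 of 20 immune cell markers were measured (camera adjusted p = 0.168; 1 rose adjusted over the list alone), of which Coro1a rose from 2 counts in the shNC libraries to 48 in shFto, a CPM ratio of 21.4 (exact 95% interval 5.61 to 182). Itgax passed only without shNC replicate 2 (adjusted p = 0.0492). Of 4 fibroblast, endothelial and epithelial markers, Col1a1 (-1.08) and Pdgfra (-0.89) fell, both at mean levels under 4 CPM (2 adjusted over the list alone; camera adjusted p = 0.561). Leaving out 1 library ended these calls in 4 of 6 cases for Col1a1 (adjusted p up to 0.112) and 5 of 6 for Pdgfra (up to 0.171), and Pdgfra did not pass with library totals (0.06). Of the lists that did not pass camera, fry called those of m6A factors (0.0142), the cell cycle (0.0142), p53 (0.0142), checkpoint ligands (0.0175), MYC (0.0249), immune markers (0.0323), chemokines (0.0429) and fatty acid synthesis (0.0429), besides class I.

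**Figure D2:**
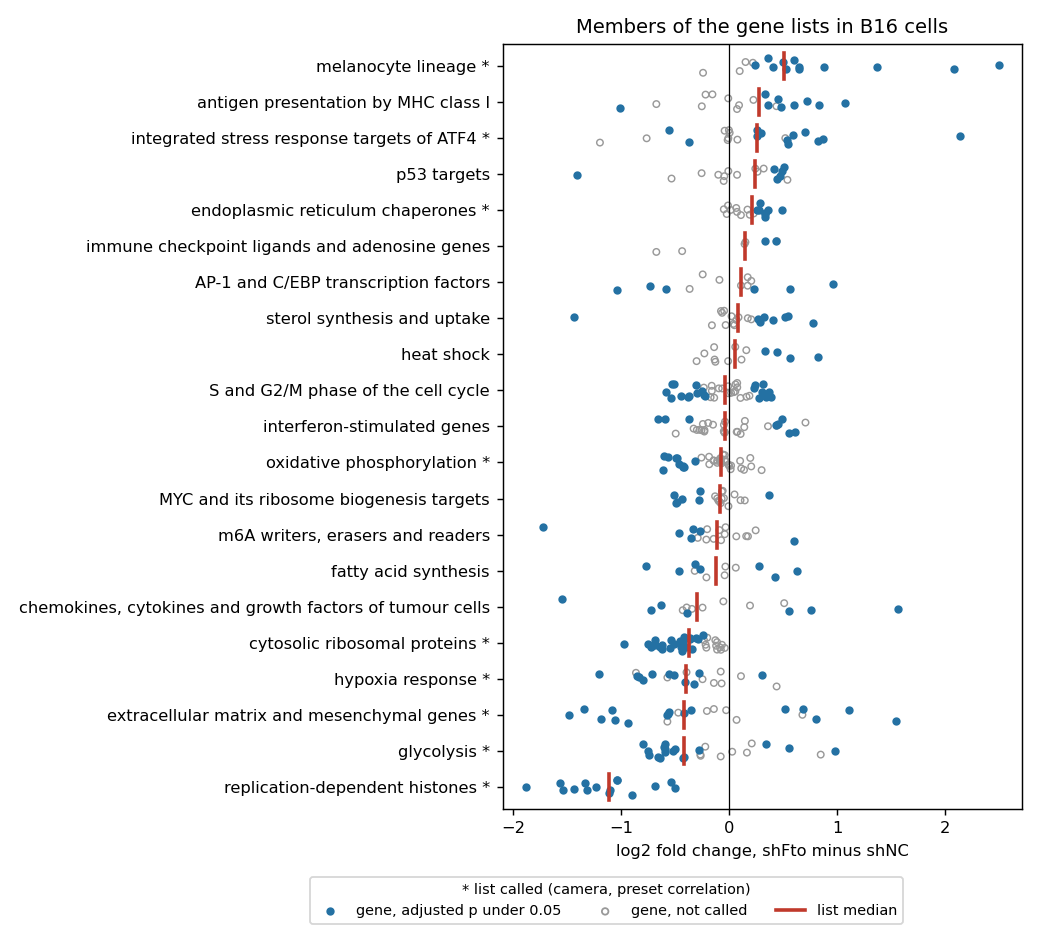
Log2 fold changes, shFto minus shNC, of the members of 21 gene lists in tumour cells. Filled points passed edgeR's test, open points did not, and red bars are list medians, which run from -1.11 for histones to 0.51 for melanocyte genes.

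Across 11718 genes, 3841 changed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 1864 higher and 1977 lower in shFto, and 381 of them at least 2-fold. With library totals in place of TMM scaling the share that was higher went from 48.5% to 60%, a shift of the median log2 fold change of all genes from -0.003 to 0.05. The count was 2468 without shFto replicate 1. The 3 shFto and 3 shNC values did not overlap for 5290 genes (45.1%), where chance gives 10%.

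The second comparison asked how T cells differed after contact with shFto tumour cells. Of 20 MYC and ribosome biogenesis genes, all 20 rose beside shFto cells (20 adjusted over the list alone), with a median log2 fold change of 1.16, while 12 of 18 effector molecules rose and 11 of 20 naive and memory genes fell. These list calls were lost at adjusted p = 0.345, 0.571 and 0.632 with an estimated correlation. The fry set test called each of these lists (adjusted p = 0.00644, 0.0136 and 0.0339), but it does not set a list against other genes. The granzyme gene Gzmb rose from 95 CPM beside shNC to 277 and 526 CPM beside shFto-1 and shFto-2 (2.00, SE 0.0912), and the inhibitory receptor gene Pdcd1, which encodes PD-1, from 11.8 to 40.8 and 81.4 CPM (2.33, SE 0.159). The interleukin 7 receptor gene Il7r fell from 421 to 166 and 82.4 CPM (-1.85, SE 0.156). These values are group means of 2 libraries, and all 3 genes had edgeR adjusted p-values from 1.75e-05 to 4e-05.

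Among the largest rises by the fixed rule, the collagen gene Col12a1 on chromosome 9 (79598987 to 79721141, mm10) had no counts beside shNC. It was at least 76.6-fold higher beside shFto-1 and at least 45.1-fold higher beside shFto-2, against a floor of 3 counts over the shNC group (edgeR adjusted p = 3.69e-05). The complement protease C1s1 (4.22), the transcription factor Cebpd (4.15), the inducible nitric oxide synthase Nos2 (3.63), the cystine transporter Slc7a11 (3.06), Ubxn8 (3.04), the calcium sensor Ncs1 (2.89) and the inhibitory receptor Lag3 (2.86) also rose. Slc7a11 and Cebpd had no counts in shNC replicates 1 and 2, respectively. Without shNC replicate 2 the values of Cebpd, Ubxn8 and Slc7a11 were 2.52, 1.88 and 9.87, and without shNC replicate 1 those of Cebpd and Ubxn8 were 10.00 and 4.59. The 9.87 and the 10.00 were fitted against libraries without counts and give no size. DESeq2 gave Cebpd an adjusted p of 0.0638.

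Crbn, a ubiquitin ligase receptor gene on chromosome 6 (106778244 to 106800099, mm10), and Sla2, an adaptor of T cell receptor signalling, had no counts beside shFto-2. There they were at least 261-fold and at least 183-fold lower than beside shNC, against a floor of 3 counts over the shFto-2 group. Beside shFto-1 they fell by 2.38 and 2.00 on the log2 scale (edgeR adjusted p = 0.00803 and 0.00319). There Crbn had 188 counts in replicate 1 and 15 in replicate 2 (15.2 and 2.96 CPM), so the size of its fall is uncertain. Why genes counted well elsewhere had no counts in a whole group was not tested. The kinase gene Matk had 3 counts beside shFto-2 and 219 beside shNC, a CPM ratio of 111 (exact 95% interval 37.5 to 543), and fell by 1.35 beside shFto-1. Clvs1 (-2.70), Nlrc3 (-2.19), Prkg2 (-2.06) and Hbp1 (-2.02) also fell in the mean of both lines. Hbp1 fell beside shFto-2 (-3.30, adjusted p = 0.000709) and did not pass beside shFto-1 (-0.74, 0.264). EdgeR adjusted p-values of these means lay between 5.43e-05 and 0.00256.

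The 20 MYC list members included nucleolin (Ncl, 1.22), Mybbp1a (1.33) and nucleophosmin (Npm1, 1.13). Camera gave the list an adjusted p of 9.48e-32, and adjusted p = 0.345 with an estimated correlation. Of 18 effector molecules, 12 rose and 2 fell (12 and 4 adjusted over the list alone), including Gzmb, the granzyme B inhibitor Serpinb9 (1.58) and the chemokine Ccl3 (1.09). Its camera adjusted p was 7.42e-07, and adjusted p = 0.571 with an estimated correlation. Of 20 naive and memory genes, 11 fell and 2 rose (13 and 2 adjusted over the list alone), including Il7r, Klf3 (-1.56) and the Wnt effector Lef1 (-1.20). This list had a camera adjusted p of 3.19e-06, and adjusted p = 0.632 with an estimated correlation. Of 25 early response genes of the T cell receptor, 11 rose, including Spry1 (1.48), Irf8 (1.07) and Tnfrsf9 (1.44), and 3 fell (12 and 4 adjusted over the list alone). That list had a camera adjusted p of 0.0456, and adjusted p = 0.683 with an estimated correlation. With library totals its median went from 0.17 to -0.005 (camera adjusted p = 0.226). The call was also lost with the replicate block (0.149), relative log expression (0.0797), thinning (0.173) and the fit without tumour-accountable genes (0.0797). The call also ended without shFto-1 replicate 1 (adjusted p = 0.0535), without shFto-2 replicate 1 (0.111) and without shNC replicate 2 (0.110; median 0.31), and the median was 0.11 without shFto-2 replicate 2.

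Of 18 endoplasmic reticulum chaperones, 12 rose and 2 fell (13 and 2 adjusted over the list alone), including Hyou1 (1.06), Canx (0.73) and Calr (0.68). Camera gave them an adjusted p of 0.00299, and adjusted p = 0.571 with an estimated correlation. Of 14 heat shock genes, 8 rose (8 adjusted over the list alone), including Hsp90ab1 (0.90), Hspd1 (1.10) and Hsp90aa1 (0.87). Camera gave an adjusted p of 0.00129, and adjusted p = 0.571 with an estimated correlation. Of 19 ATF4 targets, 8 rose and 1 fell (9 and 2 adjusted over the list alone), including the folate enzymes Shmt2 (1.46) and Mthfd2 (1.06) and the amino acid transporter Slc7a5 (1.15). The camera adjusted p was 0.00455, and adjusted p = 0.571 with an estimated correlation. The median of 0.27 became 0.63 without shNC replicate 2, 0.44 without shFto-1 replicate 1 and 0.43 without shFto-2 replicate 2. Of 36 oxidative phosphorylation genes, 14 rose and none fell (18 and 0 adjusted over the list alone), including Atp5b (0.78), Uqcrfs1 (0.93) and cytochrome c (Cycs, 0.78). Their camera adjusted p was 0.0012, and adjusted p = 0.683 with an estimated correlation. Of 35 ribosomal protein genes, 13 rose and none fell (16 and 0 adjusted over the list alone), including Rpl14 (0.51), Rps2 (0.68) and Rpl35 (0.60). The camera adjusted p was 0.00732, and adjusted p = 0.754 with an estimated correlation. Fry gave 0.138. Without shNC replicate 2 the camera value was 0.0526, and the median of 0.24 became 0.37 without shNC replicate 1. Of 19 sterol genes, 11 rose (11 adjusted over the list alone), including Idi1 (1.57), Fdps (0.83) and Lss (1.02). They had a camera adjusted p of 0.0108, and adjusted p = 0.647 with an estimated correlation. Thinning all libraries to the total of the smallest, chosen after the data were seen, ended that call (adjusted p = 0.0772).

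Of 36 interferon-stimulated genes, 14 fell and 8 rose (15 and 10 adjusted over the list alone). Those that fell included the guanylate-binding proteins Gbp4 (-1.31) and Gbp7 (-1.02). Camera placed the list lower (adjusted p = 0.0129), while its median was 0.005 and its mean -0.09, so median and test differed in sign. The call was lost at adjusted p = 0.689 with an estimated correlation, at 0.151 with fry, and at 0.0748 without shNC replicate 2, where the median was 0.10. The median was -0.14 without shFto-2 replicate 1 and -0.15 without shNC replicate 1. Guanylate-binding proteins form a family of similar genes, so single members are uncertain.

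The other T cell lists did not pass camera. Of 24 glycolysis genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.0767), among them hexokinase 2 (Hk2, 1.02), Pgam1 (0.79) and the kinase gene Pdk1 (-0.88). With no filter this list passed camera (0.0085). Of 15 inhibitory receptor and exhaustion genes, 7 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0767), among them Pdcd1, Cd200 (2.07) and Ikzf2 (-1.43). It passed camera with no filter (0.0176), without shFto-1 replicate 2 (0.0196) and without shFto-2 replicate 2 (0.0425). Of 14 AP-1 and C/EBP factors, 5 rose, including Fosl1 (1.27), Atf3 (0.97) and Cebpb (0.97, SE 0.115, adjusted p = 0.000175), and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0767). Jun (-0.30, SE 0.108, adjusted p = 0.0607) and Junb (-0.26, SE 0.105, adjusted p = 0.0876) did not pass edgeR's test. Both passed it with the replicate block (adjusted p = 0.0231 and 0.0423), relative log expression (0.0332 and 0.0395), library totals (0.00702 and 0.00697), no filter (0.0132 and 0.0381) and thinning (0.0163 and 0.0364), and both passed DESeq2 (0.0052 and 0.00816). Beside shFto-2 both fell (-0.59 and -0.44, adjusted p = 0.00479 and 0.0177), and beside shFto-1 neither passed (0.995 and 0.748). Jun also passed with the 1 CPM filter (0.0471), without tumour-accountable genes (0.0473) and without shFto-2 replicate 1 (0.00377), and Junb without shFto-1 replicate 1 (0.0244). The list passed camera with no filter (0.0312) and without shNC replicate 1 (0.0141). Of 20 hypoxia response genes, 6 rose, including Car12 (2.11) and Fam162a (0.69), and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.934). Of 36 S and G2/M phase genes, 5 rose, including the replication helicase genes Mcm2 (0.93), Mcm3 (0.83) and Mcm5 (0.84), and 7 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.934). In the mean of both lines none of 17 histone genes changed (0 adjusted over the list alone; camera adjusted p = 0.879), with values of -0.37 for Hist1h1c and -0.34 for Hist1h1e (adjusted p = 0.0518 and 0.063). These 2 genes passed with the replicate block (adjusted p = 0.0037 and 0.0131), relative log expression (0.0297 and 0.033), library totals (0.00629 and 0.00694), no filter (0.00108 and 0.00451), the 1 CPM filter (0.0383 and 0.0467), DESeq2 (0.00372 and 0.00509) and thinning (0.0129 and 0.0198). They also passed without shFto-1 replicate 1 (0.0172 and 0.0124) and without shFto-2 replicate 1 (0.0171 and 0.0297), and Hist1h1c without tumour-accountable genes (0.0403) and without shNC replicate 2 (0.0335). By line, Hist1h1c (-0.84, adjusted p = 0.00188) and Hist1h1e (-0.78, 0.00227) fell beside shFto-2 and did not pass beside shFto-1 (0.728 and 0.687), while Hist1h3e rose beside shFto-1 (1.14, 0.0206) and did not pass beside shFto-2 (0.572). In the mean of both lines Hist1h3e passed with no filter (0.0425) and without shFto-1 replicate 2 (0.026). Of 12 fatty acid synthesis genes, 3 rose, including Fasn (1.04) and Acly (0.84), and 3 fell, including Scd2 (-1.11) (3 and 3 adjusted over the list alone; camera adjusted p = 0.915). Of 19 m6A factors, 7 rose, including Hnrnpc (0.68), Ythdf2 (0.49) and Hnrnpa2b1 (0.37) (7 adjusted over the list alone; camera adjusted p = 0.285, and 0.0417 with no filter). Hnrnpa2b1 did not pass with library totals (adjusted p = 0.0897) or beside shFto-1 alone (0.124).

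Of 22 effector transcription factor and cytokine signalling genes, 7 rose, including Irf4 (0.64) and Zeb2 (0.75), and 9 fell, including Il18r1 (-1.40) (8 and 10 adjusted over the list alone; camera adjusted p = 0.554). Of 16 T cell identity genes, 4 rose, including Cd6 (0.89) and Cd5 (0.83), and 9 fell, including Cd2 (-0.67) (4 and 10 adjusted over the list alone; camera adjusted p = 0.279). Of 20 markers of B, myeloid, natural killer and CD4 cells, which a CD8 sort should remove, 6 were measured. Cd74 rose from 1.23 CPM to 9.34 and 9.05 CPM (2.65), and the other 5 did not pass (1 risen adjusted over the list alone; camera adjusted p = 0.977). Without shNC replicate 2 the Cd74 value was 4.66. Of the T cell lists that did not pass camera, fry called glycolysis (0.0306), m6A factors (0.0337) and exhaustion (0.0447), besides melanocyte genes.

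Tumour RNA was measurable in the sorted T cells. Of 18 measured melanocyte genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0542), including Pmel (2.15), Bcl2a1b (1.20), which T cells can also express and which has near-identical copies, and Tyrp1 (0.68). The list passed camera with the replicate block (adjusted p = 0.048), no filter (0.0156), the 1 CPM filter (0.0363), and without shFto-1 replicate 2 (0.0196), shFto-2 replicate 1 (0.0239) or shNC replicate 2 (0.0132), and passed fry (0.0483). Over 14 abundant melanocyte transcripts, the median level in T cell libraries beside shFto was 8.38% to 9.73% of the shFto tumour cell level. Beside shNC it was 9.65% and 10.9% of the shNC tumour cell level. Single transcripts differed widely from this median. Pmel lay at 1.33% and 1.48% beside shNC and at 4.59% to 5.36% beside shFto. Trpm1 lay at 11.2% and 10.1% beside shNC and at 2.29% to 4.81% beside shFto. The share is therefore a rough measure. The median log2 fold change of 13 of these transcripts, without the T cell gene Rab27a, was 0.30 (bootstrap 95% interval 0.03 to 0.37). Tumour RNA at that share could account for a fraction of at least 0.5 of the T cell level of 1510 genes, of which 199 changed, Clvs1 among them. Of the other 11314 genes, 4021 changed. The labels give no co-culture for the tumour cell libraries, so tumour RNA that changed during co-culture is not covered by this estimate.

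**Figure D3:**
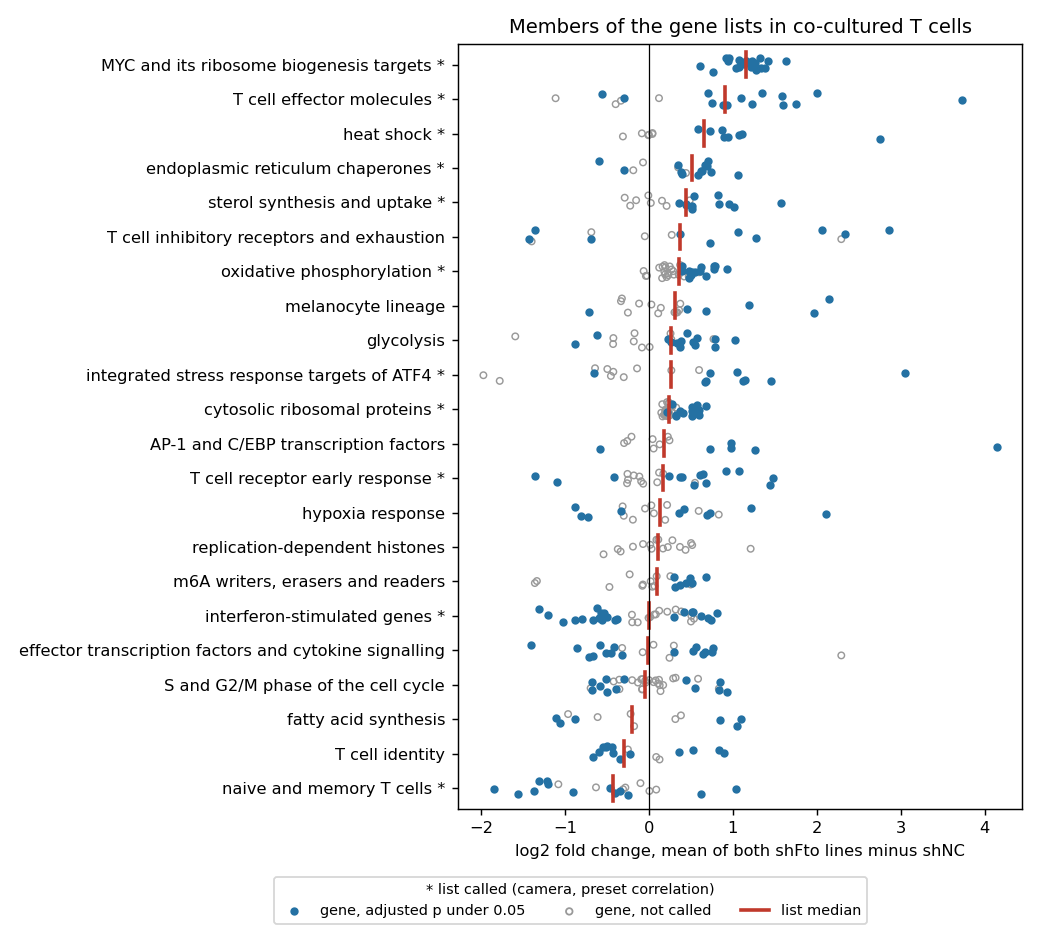
Log2 fold changes in T cells, the mean of both shFto lines minus shNC, of the members of 22 gene lists. Filled points passed edgeR's test, open points did not, and red bars are list medians, from -0.43 for naive and memory genes to 1.16 for the MYC list.

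Across 12824 genes, 4220 changed in T cells beside both shFto lines together (edgeR quasi-likelihood, adjusted p under 0.05), 2597 higher and 1623 lower, and 1054 at least 2-fold. With library totals the share that was higher went from 61.5% to 42.8%, because that scaling moved the median log2 fold change of all genes from -0.01 to -0.18. Directions here are relative to TMM scaling. Against shNC alone, shFto-1 gave 2853 genes (1976 higher, 877 lower) and shFto-2 gave 4322 (2616 higher, 1706 lower). With library totals the shares that were higher went from 69.3% to 45.7% and from 60.5% to 44.8%. The shFto-1 count was 1587 without shFto-1 replicate 1.

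The lines shared their shNC libraries, so their fold changes correlate without any effect. Across genes, which are not independent replicates, Pearson's r was 0.759 with a covariance of 1.14, against 0.541 and 0.444 in 20 simulations of unchanged groups. Both lines called 1835 genes higher and 828 lower, and none in opposite directions. Independent lists of these sizes would share 403 and 117. Simulated unchanged groups called too few genes to give an overlap. The controls were not split, since each part would hold 1 shNC library, so part of the excess may come from them. The lines differed from each other at 245 genes, 182 higher (74.3%) and 63 lower in shFto-1. DESeq2 called 1088, of which 50.8% were higher, and the count was 838 with no filter, 446 with the replicate block, 460 with crossed numbers, 147 with relative log expression and 56 at 2-fold or more. Without shFto-1 replicate 1 this count was 1, without shFto-2 replicate 2 it was 68, without shFto-2 replicate 1 it was 507 and without shNC replicate 1 it was 380.

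The third comparison asked whether open chromatin differed with Fto knockdown. The promoters of Fto, Jun, Junb and Cebpb carried an ATAC-seq peak within 1 kb of the start in all 6 libraries. So did 20 of 25 glycolysis genes, 7 of them placed by their start and the others by either end of the gene. Ldha, the lactate dehydrogenase gene, had a peak in 2 of 3 shFto and 1 of 3 shNC libraries, and Hk1, Pfkfb4, Aldoa and Slc16a3 had none at their annotated start. The shFto libraries held 70508, 72055 and 67427 peaks (mean 69997 ± 2356, SD, n = 3) and the shNC libraries 81944, 77226 and 74551 (77907 ± 3743, SD, n = 3). Every shFto library had fewer than every shNC library, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Peaks covered 26.0 ± 0.656 Mb in shFto and 29.1 ± 1.66 Mb in shNC (SD, n = 3 each; exact permutation p = 0.1). For peaks with a deposited -log10 q of at least 5, the means were 66537 and 72381 (exact permutation p = 0.3). There shNC replicate 3 (66398) lay below shFto replicate 1 (67597). Peak number can vary with read depth, which was not compared here, so fewer peaks need not mean less open chromatin.

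Over the 67427 strongest peaks of each library, the merged regions numbered 88084, and 49718 of them (56.4%) had a peak in all 6 libraries. A peak in all 3 shFto and no shNC library marked 774 regions, and the reverse marked 1461. These counts depend on equal list lengths: 516 of the 774 shFto-only regions and 228 of the 1461 shNC-only regions had a peak in a longer list of the other group. Full lists gave 353 and 2511. With 1 library left out, which asks for fewer peaks, shFto-only regions numbered 1213 (without shNC replicate 3) to 1531 (without shFto replicate 3), and shNC-only regions 2019 to 2192. Jaccard overlap was 0.732 to 0.745 within shFto, 0.732 to 0.751 within shNC and 0.695 to 0.715 between the groups.

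By the fixed rule, the strongest shFto-only regions lay at chromosome 16, 38753622 to 38753997, within B4galt4, at chromosome 8, 111595801 to 111596141, within Znrf1, and at chromosome 10, 75551101 to 75551601, within Lrrc75b (mm10). B4galt4, a galactosyltransferase gene, and Lrrc75b rose in RNA (log2 fold change 0.86 and 1.10, edgeR adjusted p = 0.00843 and 0.00516). All 3 regions had a peak in a full shNC list. The strongest shNC-only regions lay at chromosome 2, 126309997 to 126310420, 10553 bp from the nearest gene end, that of Atp8b4, at chromosome 4, 86683700 to 86684103, 13483 bp from an end of the lipid droplet gene Plin2, and at chromosome 5, 52794128 to 52794637, within Zcchc4. Plin2 rose (0.24, adjusted p = 0.0492), and Zcchc4 did not pass edgeR's test (0.27, adjusted p = 0.0781). The Zcchc4 region had a peak in a full shFto list, and the other 2 did not. Exons and introns of these genes were not used here.

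Genes with an end nearest to an shFto-only region within 50 kb, 348 in number, had a mean RNA log2 fold change of 0.12 against -0.009 in other genes. The difference of 0.13 had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give, and a Benjamini-Hochberg p of 1e-05 over the 2 tests. Within 10 kb it was 0.04 (permutation p = 0.207) and within 1 kb 0.06 (0.414). By transcription starts of genes with a known strand, chosen after the data were seen, it was 0.07 (0.00904). The 663 genes nearest to shNC-only regions had a mean of -0.08 against 0.0004 in others, a difference of -0.09 (permutation p = 1e-05, again the smallest). It was -0.12 within 10 kb (1e-05), -0.25 within 1 kb (0.00037) and -0.12 by known starts (1e-05). Genes are not independent replicates, so these p-values describe genes, not cultures. The permutations did not match genes by expression or span, while fold change rose with gene span (Spearman's 0.196 across genes).

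**Figure D4:**
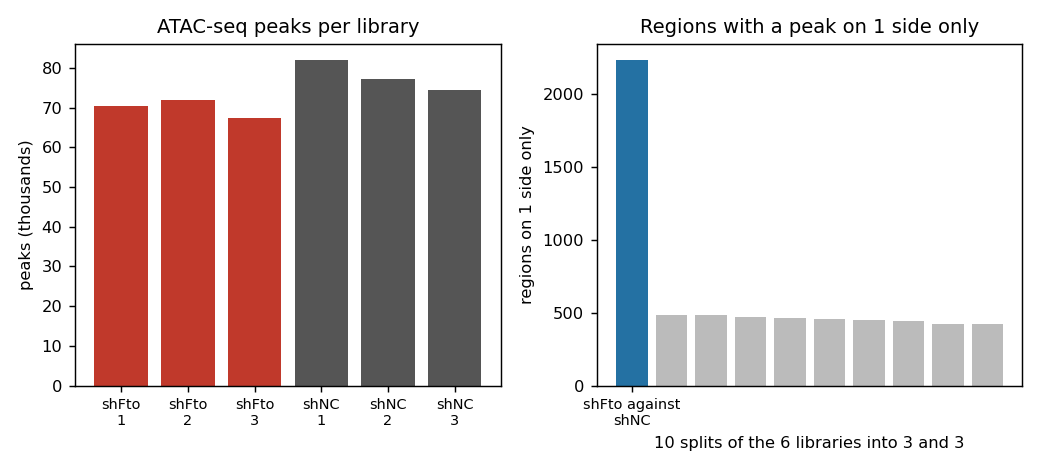
Left, ATAC-seq peaks per library on an axis from 0, with shFto in red and shNC in grey. Right, the number of regions with a peak in all 3 libraries of 1 side and none of the other for the 10 splits of the 6 libraries, where the shFto against shNC split gives 2235 and the others 423 to 488.

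The fourth comparison asked which transcripts carried m6A peaks after Fto knockdown or Dac51. With 1 library per condition, these differences have no replicate check and compare libraries, not conditions. Jun had 2 peaks in shNC, 2 in shFto and 1 in Dac51 cells, Junb 2 in each, Cebpb 1, 2 and 1, Myc 2, 2 and 3, and Fto 1 in each. Of 25 glycolysis genes, 9 had a peak in shNC and 10 in each of shFto and Dac51. Only Aldoa gained a peak in both, with an authors' fold enrichment of 1.13 in shFto and 1.27 in Dac51 cells. The lists held 8479 peaks on 5305 genes in shNC, 10811 on 6471 in shFto and 9850 on 5963 in Dac51 cells.

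The strongest peaks gained in both by the fixed rule lay in Thsd7a (chromosome 6, 12317272 to 12317392), the BMP inhibitor gene Smad6 (chromosome 9, 64021524 to 64021762), 2410004B18Rik (chromosome 3, 145943921 to 145944127), Frrs1 (chromosome 3, 116903301 to 116903540) and the mismatch repair gene Msh3 (chromosome 13, 92212359 to 92212538), all mm10. Their authors' fold enrichments in shFto were 14.6, 12.9, 12.9, 10.6 and 10.5. In RNA, Thsd7a (1.06) and Smad6 (1.60) rose, 2410004B18Rik fell (-0.68), and Frrs1 (-0.32, adjusted p = 0.0538) and Msh3 (-0.16, adjusted p = 0.257) did not pass edgeR's test.

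Of the shFto peaks, 66.6% (Wilson 95% interval 65.8 to 67.5) were overlapped by an shNC peak and 77.5% (76.7 to 78.3) by a Dac51 peak. Of the Dac51 peaks, 71.5% (70.6 to 72.4) were overlapped by an shNC peak and 86.1% (85.4 to 86.8) by an shFto peak. These intervals cover counting error only. With equal list lengths the shares of shFto peaks overlapped by shNC and Dac51 peaks were 79.8% and 86.0%. At 50 percent reciprocal overlap they were 54.5% and 66.2%. Of the shNC peaks, 88.7% were overlapped by an shFto peak. Of 6541 genes tested in RNA with no shNC peak, 685 had a peak in both shFto and Dac51, 684 in shFto alone and 360 in Dac51 alone. Independent gains would give 219 in both (odds ratio 13.4, Fisher's exact p = 1.79e-270), but both share the shNC list, so the overlap is not independent evidence. In 5 strata of expression the odds ratio ran from 9.94 to 22.8. In the other direction, 193 genes had a peak in shNC alone. With the 8479 strongest peaks of each list, 397 genes gained a peak in both and 336 had one in shNC alone.

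The 685 genes with a gained peak had a median RNA log2 fold change of 0.03 after Fto knockdown, against -0.003 expected from genes of similar expression (two-sided permutation p = 0.0154). Of them 139 rose and 91 fell by edgeR. For the 567 with a mean of at least 10 CPM the difference was 0.007 (permutation p = 0.574). Other settings kept a small difference across genes, which are not independent replicates. It was 0.06 with means (permutation p = 4e-05) and 0.04 with equal list lengths (0.0338). For genes with a peak in shFto and none in shNC it was 0.05 (1e-05).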

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

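The tests below of TMM scaling, depth, the first shNC library, melanocyte transcripts and other splits of the tumour RNA-seq libraries were chosen only after the result was seen, while those of gene span, the tumour cells' own change and the ATAC-seq splits were written before. T cells met 2 shFto tumour lines, and a direct test between the lines found 245 genes that differed. What singled out each result in the next paragraphs is this difference between groups, in edgeR's test or in camera, and values are shFto-1 minus shFto-2 on the log2 scale.

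Of 87 named genes, 25 differed, and 24 of these lay further from shNC beside shFto-2. Those reported here follow. Gzmb (-0.93), Pdcd1 (-0.98) and Nos2 (-1.56) were lower beside shFto-1. The naive and memory genes Klf3 (1.02), Il7r (0.99) and Lef1 (0.83) were higher there, and so were Ikzf2 (0.78) of the inhibitory receptor list and Il18r1 (0.94) of the effector transcription factor list. So were the interferon-stimulated genes Gbp4 (0.73) and Gbp7 (0.59), and Pdk1 (0.45), Jun (0.59) and Hbp1 (2.56). Ncl (-0.40) and Mybbp1a (-0.46) of the MYC list, Hsp90ab1 (-0.32) and Hspd1 (-0.53) of the heat shock list and Spry1 (-0.48) of the T cell receptor list were lower beside shFto-1. The histone genes Hist1h1c (0.94), Hist1h1e (0.88) and Hist1h3e (1.42) were higher there, the last being the exception to the larger change beside shFto-2. Crbn and Sla2, with no counts beside shFto-2, were higher beside shFto-1 by at least 5.88 and 5.52, and Matk by a pooled ratio of 5.41. Adjusted p-values ran from 0.0186 to 0.0499.

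Of 23 lists, 9 differed by camera. Median differences were 1.14 for histones (adjusted p = 1.3e-09), 0.28 for ribosomal proteins (3.38e-06), 0.30 for naive and memory genes (2.35e-08), 0.27 for S and G2/M phase genes (0.0396), and 0.21 for both effector transcription factors (0.00098) and T cell identity (0.00239). They were -0.33 for the MYC list (4.49e-13), -0.23 for heat shock (0.00239) and -0.17 for endoplasmic reticulum chaperones (0.0279). None of the 9 held at adjusted p = 0.638 with an estimated correlation (0.738 for ribosomal proteins). The gene count was 1 without shFto-1 replicate 1, so the difference between lines rests on few libraries.

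The first pattern weighed was the fall of glycolysis, ribosomal protein and histone transcripts in shFto tumour cells. Fold change rose with gene span (Spearman's 0.196 across genes), and median spans were 19.8, 3.61 and 0.502 kb against 23.3 kb for all genes. After removal of the trends with span and level, glycolysis had a median of -0.28 (bootstrap 95% interval -0.45 to -0.10) and ribosomal proteins -0.14 (-0.22 to -0.03). Such a trend may therefore account for part of both falls, and whether for more than a fraction of 0.5 could not be told. Histones kept -0.89 (-1.22 to -0.82), and library totals left glycolysis at -0.36. The fitted span trend therefore does not account for most of the histone fall, nor scaling for that of glycolysis. Histones lie at the short end of the spans, where a trend smoothed over 30% of genes may miss a steeper effect. A larger effect of very short span is thus not excluded, and the interval treats 15 similar genes as independent. An effect of Fto knockdown remains possible.

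The second pattern was the rise of MYC target and effector transcripts in T cells beside shFto cells. The MYC median of 1.16 stayed at 1.10 with all libraries thinned to equal totals and at 1.14 without the first shNC library. Abundant melanocyte transcripts had a median of 0.30 (0.03 to 0.37), below the MYC median. Melanocyte lineage genes also rose in shFto tumour cells (median 0.51), so that value mixes tumour share with the tumour cells' own change. Set against tumour cells of the same hairpin group, the share was 8.38% to 9.73% beside shFto. Beside shNC it was 9.65% and 10.9%. This median share was not higher beside shFto, so by that measure more tumour RNA is unlikely to explain the rise. The measure is rough, since single transcripts such as Pmel and Trpm1 moved in opposite directions. A response to shFto tumour cells could explain it, but whether 2 libraries per line came from separate cultures is not stated.

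The third pattern was the set of tumour transcripts that differed between the T cell co-cultures, with Pmel (2.15) among them. The other abundant melanocyte transcripts had a median of 0.22 (-0.04 to 0.37), which also holds the tumour cells' own change. Set against tumour cells of the same hairpin group, the median share of tumour RNA was not higher beside shFto. By that rough measure, a larger share alone is unlikely to explain Pmel. Of 113 genes that tumour RNA can account for and that changed in both comparisons, 74 changed the same way, 65.5% (Wilson 95% interval 56.3 to 73.6), below the 75% set beforehand for the tumour cells' own change as the cause. For other genes the share was 36.5% (34.0 to 39.1), so that change may still contribute.

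Other splits of the 6 libraries tested whether grouping alone could give such results. In tumour RNA-seq the real split was the only 1 of 10 to reach 3841 genes, and the highest other count by edgeR was 0, with 42 to 617 genes at unadjusted p under 0.05. For lists, the real split gave 9 and the highest other 8. Every other split mixed shFto and shNC libraries unequally on each side, so part of the real difference remained in it. The mixing also widened the spread within each side. Whether camera with its preset correlation calls many lists by chance can therefore not be told from these splits. For ATAC-seq, the real split gave 2235 regions and the highest other 488. With 10 splits the smallest share is 0.1, so the splits cannot tell.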

How the results depend on the processing

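The only tests here chosen after the result was seen were the T cell fits that were thinned, that left out tumour-accountable genes or that crossed replicate numbers, and starts of known strand. No named gene that passed its test changed sign. With library totals the share of changed T cell genes that were higher turned from most to 42.8%, and to 45.7% and 44.8% for shFto-1 and shFto-2, because that scaling moved the median of all genes; the T cell receptor list median became -0.005. Of the named genes, 76 of 82 in tumour cells and 80 of 87 in T cells kept their call, or lack of one, under every alternative. So did 6 of 23 and 7 of 23 lists. The 7 T cell lists were not called to begin with, since every called T cell list lost its call with an estimated correlation. In tumour cells all called lists but 1 lost theirs in that test. Among 978 and 1208 alternative values of named genes, 962 and 1168 were the same. DESeq2 shared 3702 of 3841 tumour cell calls and 4035 of 4220 T cell calls. The smallest T cell library held 2628158 counts, and thinning all to that total left 3962 genes changed. Where 1 library was left in a T cell group, it was assumed to vary like the other groups.

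With an estimated correlation 1 tumour cell list and 0 T cell lists were called. Fry called 15 in tumour cells and 13 in T cells. It asks a different question, whether a list changed at all, where 32.8% of tumour cell and 32.9% of T cell genes changed. What else set these counts apart was not tested. A 2-fold threshold left 381 genes in tumour cells, 1054 for both lines, 490 for shFto-1, 1557 for shFto-2 and 56 between lines, as its construction requires. The count between lines was 147 with relative log expression, 838 with no filter and 1088 with DESeq2; the cause was not tested. With a library left out, counts were 2468 to 4423 in tumour cells, 1587 to 2878 for shFto-1, 1 to 507 between lines, and 1213 to 1531 and 2019 to 2192 for shFto-only and shNC-only regions, with fewer samples.

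Replicate numbers did not pair the tumour libraries: their same-number correlations were 0.014, 0.037 and -0.017, so not every library correlated best with its own number. With the replicate block 3736 genes changed in tumour cells, 4223 in T cells and 446 between lines. In T cells same-number correlations were 0.37 between the shFto lines and -0.32 and -0.21 with shNC. Replicate 1 of shFto-1 lay closer to replicate 1 of shFto-2 (Spearman's 0.986) than to replicate 2 of its own line (0.976). Replicate 2 of shFto-1 and of shFto-2 gave 0.973. The main T cell fit had no block for replicate number. With crossed shNC numbers in the block, chosen after the data were seen, the counts were 4459 and 460.

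Regions numbered 353 (shFto-only) and 2511 (shNC-only) with full lists, and 495 and 908 with fewer peaks per library. At a -log10 q of at least 5 they numbered 350 and 2096. The RNA difference by shFto-only regions was 0.0442 within 10 kb (permutation p = 0.207) and 0.0601 within 1 kb (0.414), with fewer genes. A fold enrichment of at least 4 left 5064, 7043 and 6180 m6A peaks in shNC, shFto and Dac51, and equal list lengths left 397 genes gained in both. At 10 CPM or more the RNA difference was 0.00688 (permutation p = 0.574); the cause was not tested. Motif, m6A sequence and transcript location analyses were not run.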

Other observations

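The observations below were singled out after their values were seen, and no tests were added for them. Among the interferon-stimulated genes of T cells, Gbp4 (-1.31), Igtp (-0.88), Gbp2 (-0.80) and Irgm1 (-0.61) fell beside shFto cells. In the same list Usp18 (0.81), Dhx58 (0.74), Mx2 (0.70), Oas2 (0.53) and Ifit1 (0.52) rose. Among effector genes, Ifng (0.88), Prf1 (1.76) and Il2 (0.70) rose, while Tnf (-0.55) and Ccl5 (-0.30) fell.

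Some genes moved the same way in tumour cells and in the T cells that had met them. Prkg2 fell in both (-2.72 and -2.06), and its T cell level beside shNC, 39.0 CPM, was at or above the 33.4 CPM of shNC tumour cells. Slc7a11 rose in both (2.14 and 3.06). Col12a1 rose in both, from 3.12 to 14.7 CPM in tumour cells and from no counts in T cells. Met, a receptor tyrosine kinase gene, rose by 1.72 in tumour cells and 2.82 in T cells.

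With at least 10 counts in every other T cell library, 4 genes had no counts beside shFto-2 (Sla2, Acot11, Crbn and Dand5). Beside shNC the same held for 8 genes (AI607873, Nr1d1, Piwil2, Mpeg1, Dnajc19, Alpl, Fam20c and Col12a1), and beside shFto-1 for 0. Why these genes had no counts was not tested.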
